A study of Mus musculus with 6 samples.

How the data were processed

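Messenger RNA libraries were prepared with a stranded kit from total RNA of cultured SSC, iGSC and FGSC, per the labels' protocols. The submitters' processing notes name HISAT2 version 4.8.2, Cufflinks version 2.2.1 and the genome build mm9, without saying what each was used for. The authors deposited 1 table for the whole series, with a gene name, a genomic position and 6 value columns. The unit of the values is not given in the table, and the values were not analysed here.

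The column names were compared with the title, description, source name and characteristics of each sample. The number of value columns that could not be matched to a sample or a cell type was 6. Column order and the expression values themselves, including those of sex-linked genes, were not used to assign them. No label tied a column to a sample. The tests planned before the data were examined (limma on log2 values, gene list tests and the position of iGSC between SSC and FGSC) were therefore not run.

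The gene names and positions were read with Python 3.11.15 and pandas 2.3.3. Of the 24537 gene names with a single row and no number in place of a name, 24047 had exactly 1 RefSeq gene of that name in the GRCm38 assembly. Of these, 23984 lay on the same chromosome, but only 2734 (11.4%) overlapped the GRCm38 gene by at least 1 base. The positions were thus not those of GRCm38, and no coordinates are printed. No mm9 annotation was used here.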

Results

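RNA sequencing was described for 6 libraries of cultured mouse germline cells. They comprised 3 cell types with 2 libraries each. Spermatogonial stem cells (SSC) are the self-renewing germ cells of the testis. Another line was labelled as female germline stem cells (FGSC), and the third line was labelled as induced germline stem cells (iGSC). The lines were of the C57BL/6 strain, had been carried for more than 20 passages, and were grown on STO feeder cells, a mouse embryonic fibroblast line. Nothing in the labels said whether the 2 libraries of a cell type came from separate cultures.

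The design implied 3 comparisons, namely iGSC against SSC, FGSC against SSC, and iGSC against FGSC. None of the 3 was made. The deposited expression table named its 6 value columns by 3 codes, each with a first and a second replicate. None of the codes occurred in the labels of any of the 6 samples, and each replicate word occurred in the labels of 3 samples. The columns were therefore not assigned to a cell type, and no expression value, fold change or test result is reported. The sequencing depth of the libraries was not determined here.

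The table listed 25454 rows under 24869 distinct entries in its gene name column, and 585 rows repeated an entry already used. Both counts include bare numbers that stood in place of a name. In 26 rows the gene name was a bare number, as a spreadsheet writes a date, with 24 different numbers among them. Of the 818 entries in the gene lists drawn up for the comparisons, 801 were named in the table. All 37 spermatogonial stem cell genes, all 30 pan-germ cell genes, all 36 oocyte genes, all 12 Y-linked genes and all 33 fibroblast genes were listed. The meiosis list had 28 of its 29 genes in the table, and the Sertoli cell list had 18 of its 19. The paternally expressed imprinted list had 32 of its 34. None of the 13 protein-coding genes of the mitochondrial genome was listed under the symbols used. A name in the table does not show that the gene was expressed.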

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

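No paired analysis was possible for the cell types, because the value columns could not be tied to them. For that reason no other setting of the expression tests was run either. The same replicate numbers recurred in every cell type, but shared numbers alone do not show that libraries were paired. Comparisons between the column codes, without cell types, were not run. The check of gene positions, chosen after seeing the data, was repeated with GENCODE M21 genes in place of RefSeq genes. Of 24032 gene names, 2758 (11.5%) then overlapped the GRCm38 gene of that name, against 11.4% with RefSeq. Both gene sets describe the GRCm38 assembly, so similar shares were likely from the start. The repeat could not test the stated build mm9.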
